A study of Mus musculus with 188 samples.

How the data were processed

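Single keratinocytes were sorted from mouse tail epidermis at postnatal day 20, 1 cell per well, and each well became a Smart-seq2 library, a method that copies polyadenylated RNA into full-length cDNA before fragmentation. Per the labels' protocols, the gate kept cells without surface CD34, with integrin alpha 6 and without the yellow fluorescent protein of an Lrig1-CreERT2 reporter strain, which targets basal cells of the interfollicular epidermis. ERCC spike-in RNA was added to the lysis buffer, Nextera indexes marked the wells, and the pooled libraries were sequenced together, per the labels' protocols. Each sample is 1 cell, 94 on each of 2 plates, and all form 1 group. No label names an animal, so the group was treated as 1 sample. No p-value or standard error was computed, since cells are not replicates.

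The values are whole-number read counts per gene, deposited by the authors as raw counts without normalization. The submitters' processing notes name cutadapt 1.13, STAR 2.5.2b, HTSeq 0.6.0 and GRCm38. Their order, their parameters and the annotation release are not given in the sources used here. The table holds 49585 gene rows and 92 spike-in rows, and no column was left unused. Symbols were taken from a table of mouse gene names, which matched 49326 of the identifiers without their version. Positions come from GENCODE M21 on GRCm38. Whole-read counts without molecular identifiers count amplified copies, so all intervals and floors cover counting error only. The counting is not stated to use strand, so reads of overlapping or antisense genes cannot be told apart, and reads shared by close paralogs such as Krt6a and Krt6b are uncertain.

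Counts were divided by each cell's total over genes and scaled to CPM, with spike-ins left out. Cells were kept with at least 50000 counts, at least 1500 genes with a read and at most 15% mitochondrial counts. No doublet caller was run, because 1 cell was sorted per well, and leaving out the 5% of cells with most genes served as the check. A cell would have been called a non-keratinocyte with at least 3 genes, and at least 50% of the list, of the T cell, Langerhans cell, melanocyte, Merkel cell, fibroblast or endothelial cell list at 10 CPM. The other lists were basal keratinocyte, early differentiation, late differentiation, S phase, G2/M phase, upper hair follicle, hair follicle bulge, sebaceous gland, Notch pathway, Wnt pathway, EGF receptor pathway, immediate early and heat shock, wound and stress keratinocyte, and tail compartment and lineage genes. The 20 lists hold 234 different genes and were fixed, with the tests and the rule for named genes, before the data were examined. A list score is the mean z score of log2(CPM + 1) over list genes at 10 CPM in at least 5% of cells. Genes shared with the early differentiation list were left out of the other list when the pair was compared, and a member's own value was left out of the score it was compared with.

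Relations across cells are given as Spearman's rho and Pearson's r, within each plate and without the 2 cells farthest from the median early differentiation score. A total of 13 list scores were compared with the early differentiation score. Each rho was placed among 10000 random lists in which every gene was replaced by 1 of the 50 genes nearest in mean log2(CPM + 1). Genes of random lists hardly varied together, so a list whose members vary together can more easily fall outside their range. Gene counts rest on rules of size. A gene was counted with the early differentiation score if it was outside the early differentiation list, at 10 CPM in at least 10% of cells, and its rho was at least 0.3, or at most -0.3, on both plates. The same count was made for 100 random lists. A gene was counted as variable if its mean was at least 50 CPM and its squared coefficient of variation was at least 2 times the spike-in trend, a1/mean + a0, on both plates. Clusters came from 1000 genes, 15 principal components, 10 neighbours and Leiden clustering at resolution 1. A cluster was named for a list if its mean score was at least 0.5 above that of the other cells, at least 3 members were detected in 50% of its cells and a member stood among its 10 leading genes, a rule set after the data were seen. Shares carry exact Clopper-Pearson 95% intervals, and a gene with no read the limit of 3 cells over the cells examined. Clusters were compared with the lettered rows after they had been seen. The named genes were the 25 most variable, the 15 highest and 15 lowest with the early differentiation score ranked by the plate nearer to 0, 10 per cluster, up to 5 of the most abundant per list with any member opposite in sign to its list, and 12 fixed genes. The cluster genes are given only where a cluster was named. Of the genes with the early differentiation score that the rule selects, 1 is not reported here.

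Reads carried between wells were estimated after the data were seen, by the lettered row and the column in the well labels, since the index of each well is not given in the sources used here. In 56 genes with at least 100 reads in 1 well and under 10 reads in each of the others, stray reads per source read were counted in wells of the same lettered row, of the same column and of neither, and the median over genes was taken. A total of 5 forms of this estimate were computed, and the form used was chosen after the results of others for Krt10 had been seen. The 4 others used genes at 10 reads in up to 3 wells, either in 1 weighted fit over genes with at least 100 reads, or as medians over the same genes, over 20 genes with at least 200 reads and over 4 with at least 300. Stray reads per 10000 in unrelated wells were 1.00 in the form used and 2.59 to 5.42 in the others, and the ratio of same-row to unrelated wells was 30.2 in the form used and 5.89 to 12.3 in the others. The fit and the median over the same genes also served as alternatives. The expected background of each gene and well was then computed from the counts of all other wells, and it was subtracted in an added alternative. A gene was called above background in a well at 10 CPM and more than 3 times this expected value, a rule that is hard to pass in shallow wells.

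The code was tested on simulated data with the real gene means, library sizes and spike-in noise and 200 genes changed with a hidden cell state, beside the early differentiation list itself. For the early differentiation score, where 7859 simulated genes were tested, it recovered 80.6% of the 31 genes with a mean of 50 CPM or more that changed by 1 on the log2 scale per SD of the state, and 12.5% of the 24 such genes that changed by 0.5. Below 50 CPM it recovered 0 of 35 at a change of 1 and 28.9% of 38 at a change of 2. None of 7698 unchanged genes was counted. For the variable genes, with 3697 simulated genes tested, 16 of 26 abundant genes were recovered at a change of 2 and 2 of 30 at a change of 1, with 0 of 3606 unchanged genes counted. The unchanged genes held spike-in noise only, without stray reads or variation shared between cells. These counts of 0 are therefore no rate of false calls in the real cells. Simulated stray rates of 30, 12 and 1 per 10000 were recovered as 30.2, 12.4 and 0.908. With low counts of the source genes left in, they were recovered as 46.4, 24.1 and 2.13, so low expression elsewhere inflates the estimate.

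Alternatives covered looser and stricter cell filters, single plates, cells thinned to 50000 counts, cells with most genes left out, detection limits, the class rule, log2(CPM + 10), size factors from pooled cells, adjustment for genes detected, the technical trend and the clustering settings. All 79 alternatives listed before the data were examined gave a value. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and scran 1.30.0 were used.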

Results

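The study examined how single basal keratinocytes of the tail interfollicular epidermis differ from each other and how they begin to differentiate. Read counts of single cells from day 20 were available, 94 cells from each of 2 plates, 1 cell per sample. A cell had 79868 to 1093805 counts over genes, with a median of 369991, and 5821 to 8720 genes with a read. The mitochondrial share was 2.42% to 11.8% of counts and the spike-in share 0.247% to 5.70%. The median depth was 373722 counts on plate 1 and 366461 on plate 2. All cells of both plates passed the filters, 94 on each. No 2 cells held identical counts, and the highest correlation of log2 values between any pair was 0.567. Because all cells belong to 1 group without named animals, values are spreads over cells with no test between groups.

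Most cells carried Itga6, which encodes the integrin used for sorting, and transcripts of other cell types were scarce. Itga6 exceeded 3 times the background expected from other wells in 87.8% of the cells (95% interval 82.2% to 92.1%), and was at 10 CPM or more in 100%, a share that stray reads can raise. Its mean was 646 ± 400 CPM (SD over all cells). Cd34, the bulge stem cell marker selected against, had no read in any cell, which allows a share of up to 1.60% of cells with a read. Lrig1, the gene behind the reporter selected against, reached 10 CPM in 19 cells, 10.1% (95% interval 6.21% to 15.3%). No cell met the rule for a non-keratinocyte. Over the pooled counts of all cells, the T cell list took 0.155 CPM, the Merkel cell list 0.0517 CPM, the Langerhans cell list 2.09 CPM, the endothelial list 3.19 CPM, the melanocyte list 17.1 CPM and the fibroblast list 24.9 CPM. Most fibroblast counts were of Dcn, a matrix proteoglycan, which had a mean of 25.6 CPM, while the collagen genes Col1a1 and Col1a2 had means of 0.226 and 0.164 CPM.

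The leading basal keratinocyte genes had high means. Over the 15 list members, the share of cells above background ran from 62.8% for Itga3 to 93.1% for Col17a1, by a rule that is hard to pass in shallow wells. Krt14 and Krt5, the keratin pair of the basal layer, had means of 32410 ± 14096 and 20310 ± 7609 CPM (SD over all cells). Krt15, a further basal keratin, had a mean of 5195 ± 5133 CPM, so that its SD was close to its mean. Col17a1 and Dst, both components of hemidesmosomes that anchor the cell to the basement membrane, had means of 2365 ± 1021 and 1675 ± 777 CPM. All 15 list members entered the score, and the mean rho over pairs of members was 0.336, above all 10000 random lists, whose median was 0.0111. In the mouse genome GRCm38 with GENCODE M21, Krt14 (ENSMUSG00000045545.8) lies on chromosome 11 from 100203162 to 100207548 and Krt15 on chromosome 11 from 100131758 to 100135928, both on the minus strand. Krt5 (ENSMUSG00000061527.6) lies on chromosome 15 from 101707070 to 101712898, also on the minus strand.

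Early differentiation genes varied much more between cells. Krt10 and Krt1, the keratin pair of the suprabasal layers, had medians of 882 and 874 CPM but means of 4864 ± 8809 and 2594 ± 5465 CPM (SD over all cells). Krtdap, a keratinocyte differentiation-associated protein, had a mean of 4925 ± 3675 CPM, Calm4, a calmodulin-like protein of the epidermis, 3628 ± 3267 CPM, and Dmkn, secreted by suprabasal keratinocytes, 2752 ± 1486 CPM. Mt4, a metallothionein of stratified epithelia, had a mean of 1422 ± 2312 CPM. Dsc1, a desmosomal cadherin of upper layers, reached 10 CPM in 14.4% of cells, Klk10 in 17.6% and Notch3 in 12.2%. The mean rho over pairs of the 12 members was 0.312, above all 10000 random lists. Krt10 (ENSMUSG00000019761.10) lies on chromosome 11 from 99385254 to 99389364 and Krt1 (ENSMUSG00000046834.6) on chromosome 15 from 101845426 to 101850794, both on the minus strand.

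Krt14 and Krt10 were both at 10 CPM or more in 100% of the cells (exact 95% interval 98.1% to 100%). The share cannot be read as expression, because Krt10 reads carried over from other wells would give it too. Stray reads per 10000 source reads were 30.2 in each well of the same lettered row, 12.3 in each well of the same column and 1.00 in each other well. They amounted to an expected 3.19% to 54.2% of a cell's counts, with a median of 10.1%, the lowest of 5 forms of the estimate, of which the others gave medians of 13.3% to 18.5%. Krt10 exceeded 3 times its expected background in 59 cells, 31.4% (95% interval 24.8% to 38.5%), with 25 of 94 on plate 1 and 34 of 94 on plate 2. The 4 other forms gave 25.0% to 27.7%, and the form used was chosen after results for Krt10 had been seen. By the same rule, Krt14 and Krt10 were both above background in 17 cells of plate 1 and 20 of plate 2, Krt14 alone in 67 and 58, Krt10 alone in 8 and 14, and neither in 2 and 2. The abundance of Krt14 in other wells raises its limit, which is hardest to pass in shallow wells. A cell counted with Krt10 alone or neither therefore need not lack Krt14. Krt1 was above background in 48.9% of cells and Krtdap in 85.1%.

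**Figure D1:**
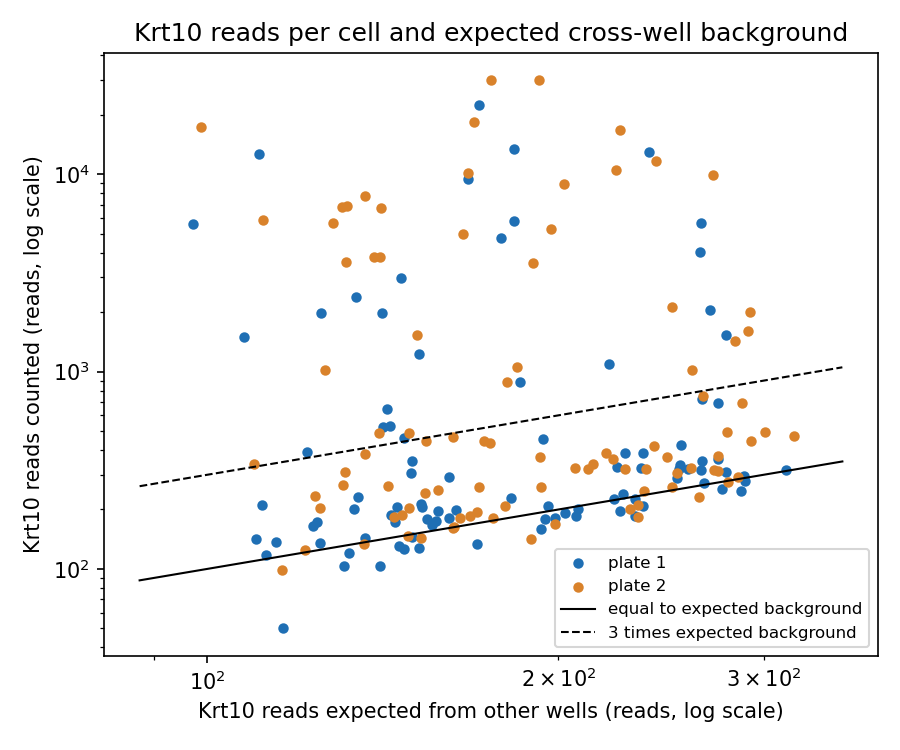
Krt10 reads counted in each cell (vertical axis, reads, log scale) against the reads expected from other wells (horizontal axis, reads, log scale), with plates in 2 colours. The solid line marks equality and the dashed line 3 times the expected background, above which 59 cells lie.

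The early differentiation score moved against the basal score across cells. Spearman's rho was -0.635 and Pearson's r -0.799 over all cells, with a rho of -0.640 on plate 1 and -0.645 on plate 2. Without the 2 cells farthest from the median, rho was -0.624 and r -0.779. All 10000 random lists matched to the basal list gave a higher rho, with a median of -0.0126. The basal genes varied together, with a mean rho over pairs of 0.336 against a random median of 0.0111. Such a list can more easily leave the range of random lists, so this place says little by itself. All 15 basal genes had a negative rho with the early differentiation score, and 10 of them were at -0.3 or below on both plates. Lamb3, a chain of an epidermal basement membrane laminin, had a rho of -0.558, Itga3, an integrin that binds it, -0.538, and Trp63, the transcription factor p63 of stratified epithelia, -0.472. Krt14, Krt15 and Krt5 had a rho of -0.478, -0.467 and -0.463, and Itga6 -0.417. Leaving out the cells of the early differentiation-like cluster, which narrows the range of the score, gave a rho of -0.365, which was -0.507 on plate 1 and -0.195 on plate 2.

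**Figure D2:**
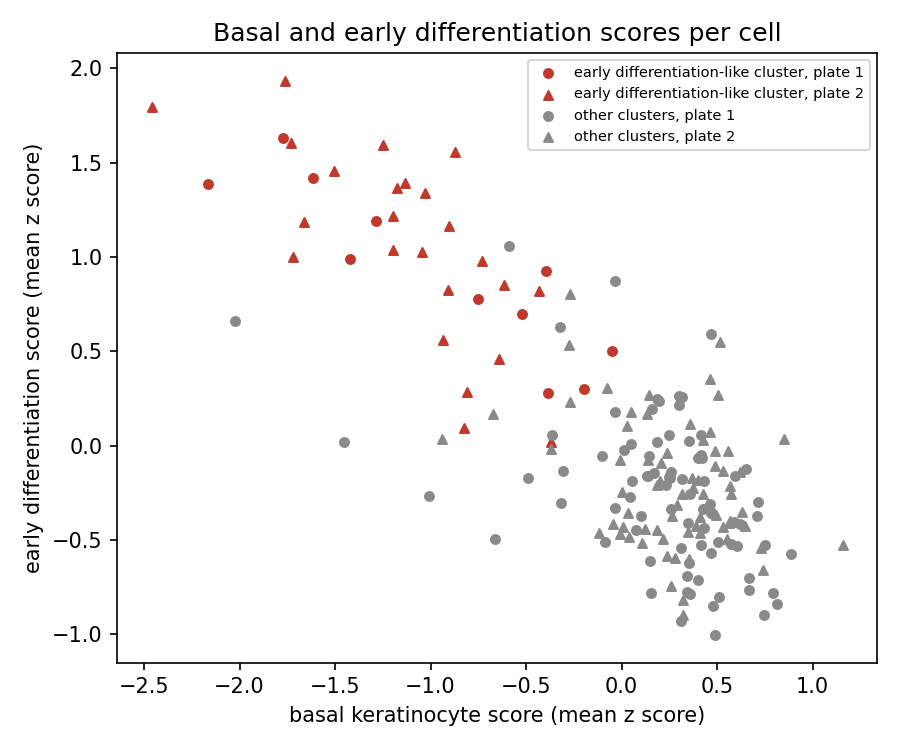
Early differentiation score (vertical axis, mean z score) against basal keratinocyte score (horizontal axis, mean z score) of each cell, with the early differentiation-like cluster in red, other cells in grey and plates as circles and triangles. The 35 cells of that cluster lie mostly at the upper left, and rho over all cells was -0.635.

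Ranked by the rho of the plate nearer to 0, Ly6d, Cdkn1a and Perp stood highest with the early differentiation score among genes outside its list. Of 9333 genes tested, 55 had a rho of at least 0.3 and 62 of at most -0.3 on both plates, against a median of 1 gene and a highest count of 8 genes for 100 random lists. Genes of random lists hardly varied together, with a median rho over pairs of 0.00778 against 0.312 for the early list. Any list of genes that vary together could therefore exceed them. With size factors from pooled cells, the split was 69 higher and 47 lower. Among the 15 highest, given with the rho of the plate nearer to 0, the first were Ly6d, a lymphocyte antigen 6 family member, at 0.660, Cdkn1a, the cell cycle inhibitor p21, at 0.560, and Perp, a p63 target in desmosomes, at 0.542. Next came Lgals3, a galectin, at 0.531, Gltp, a glycolipid transfer protein, at 0.530, Calm5 at 0.520, the transcription factor Zfp750 at 0.503, and Dbi, which binds acyl-CoA, at 0.468. The desmosomal or junctional genes Dsc3, Dsg1b, Jup and Pkp1 stood at 0.481, 0.462, 0.461 and 0.443. Lypd3 stood at 0.464 and Krt2, a keratin of late suprabasal cells, at 0.460. Ly6d (ENSMUSG00000034634.7) lies on chromosome 15 from 74762056 to 74763620.

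Of the 15 genes with the lowest rho, Tns1, which links integrins to actin, stood first at -0.573, followed among others by Itga3 at -0.527, Lamb3 at -0.503, Plec, which ties keratins to hemidesmosomes, at -0.466 and Itgb1, the beta 1 integrin chain, at -0.455. The matrix protein gene Sparc stood at -0.495 and the caveolar gene Cavin1 at -0.443. Slc2a1, the glucose transporter GLUT1, stood at -0.505, the Notch ligand Jag2 at -0.487, Dlk2 at -0.471 and the ligand Wnt10a at -0.442. Tmpo, a nuclear lamina protein, stood at -0.486, the ferritin light chain Ftl1 at -0.421, the replication helicase subunit Mcm5 at -0.420 and Ctnnal1 at -0.418. After subtraction of the background, 98 genes met the rule, 39 higher and 59 lower, and 80 genes were counted in the same direction both ways. Across genes, which are not independent, the rho values of the 2 plates correlated at 0.342.

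Late differentiation genes were scarce, and their score had a low rho with the early one. The 14 members of the list summed to a mean of 128.1 CPM, against 20720 CPM for the early list. Tgm3, a transglutaminase, had a mean of 34.8 ± 57.1 CPM, Casp14, a caspase of cornification, 27.1 ± 67.5 CPM, and Lor, the cornified envelope protein loricrin, 17.1 ± 45.4 CPM (SD over all cells). Asprv1 and Flg, the latter encoding filaggrin, reached 10 CPM in 12.2% and 7.98% of cells. The late score, from 8 members, had a rho of 0.188 and an r of 0.223 with the early score, at the 99th percentile of random lists. The rho was 0.243 on plate 1 and 0.112 on plate 2, and 0.172 without the 2 farthest cells. Casp14 had a rho of 0.288 with the early score and Lor 0.131, while Tgm3, Flg, Asprv1, Hrnr and Lce1c had -0.00713, -0.0541, -0.0100, -0.0634 and -0.0448. Of the 14 members, none was at 0.3 or above on both plates. The mean rho over pairs of the 8 scored members was 0.0220, at the 79.2nd percentile of random lists, so they hardly varied together. All members had means under 50 CPM, where the simulation recovered few changed genes, so a closer relation could be missed.

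The share of cells with transcripts of G2 and mitosis depended on the rule. At least 25% of the 33 G2/M genes were at 10 CPM in 48 cells, 25.5% (95% interval 19.5% to 32.4%), 26 on plate 1 and 22 on plate 2. This class is a range of a score, and 24 cells had between 20% and 30% of the list. The share was 57.98% with at least 10% of the list, 9.04% with at least 50%, and 93.1% with detection at 1 read. After subtraction of the background it held 33 cells, 17.6%. Mki67, the proliferation marker Ki-67, had a mean of 71.5 ± 221 CPM, Top2a, a DNA topoisomerase, 68.9 ± 225 CPM, Cdc20, an activator of the anaphase-promoting complex, 57.5 ± 214 CPM, and the centromeric histone gene Cenpa 53.9 ± 190 CPM (SD over all cells). Mki67 was above background in 42 cells and Top2a in 54. The G2/M score had a rho of -0.107 and an r of -0.128 with the early differentiation score, at the 20.3rd percentile of random lists. The rho was -0.0313 on plate 1, -0.170 on plate 2 and -0.102 without the 2 farthest cells. After subtraction of the background it was -0.194, at the 4.72nd percentile of random lists, so its place depends on the background.

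S phase genes were lower in cells with a high early differentiation score. The S phase score of 22 genes had a rho of -0.372 and an r of -0.403, below all 10000 random lists, with a rho of -0.306 on plate 1 and -0.480 on plate 2, and -0.356 without the 2 farthest cells. The S phase genes also varied together, with a mean rho over pairs of 0.295 against a random median of 0.0143. The place among random lists therefore says little by itself. All 22 members had a negative rho and 5 were at -0.3 or below over all cells. Among them, the replication helicase genes Mcm5, Mcm3 and Mcm2 had -0.413, -0.336 and -0.322. Mcm6, with a mean of 182.7 ± 228 CPM, had -0.261 and Pcna, the sliding clamp of DNA polymerase with a mean of 155.6 ± 153.6 CPM, had -0.275. Mcm5 alone was at -0.3 or below on both plates.

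The Wnt pathway score was also lower as the early differentiation score rose, and Notch pathway genes were divided. The Wnt score of 13 genes had a rho of -0.510 and an r of -0.527, at the 0.0100th percentile of random lists, with a rho of -0.432 on plate 1 and -0.602 on plate 2, and -0.498 without the 2 farthest cells. Wnt10a had a rho of -0.515 and Wls, which carries Wnt proteins to the cell surface, -0.498, both at -0.3 or below on both plates. Only these 2 of the 14 list members met that limit. The median rho of the members was -0.146, with 12 of them below 0. Wnt4, Wnt3 and Lgr6, a receptor of R-spondins, had -0.245, -0.157 and -0.271, and Ctnnb1, encoding beta-catenin, -0.0325. Fzd6 and Tcf7, at 0.0748 and 0.00970 over all cells, had the opposite sign there but were negative on plate 2. The Notch score without Notch3 had a rho of -0.197 and an r of -0.179, at the 2.74th percentile, with -0.192 and -0.244 on the 2 plates and -0.202 without the 2 farthest cells. Jag2 and Dll1, both Notch ligands, had -0.546 and -0.289, Notch1 had -0.0309, and the Notch targets Hes1 and Nrarp had 0.149 and 0.230, with 0.110 for Notch2 and 0.382 for Notch3.

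Of the stress and growth factor lists, the wound list alone had a rho with the early differentiation score outside the central 95% of random lists. Its score of 5 genes had a rho of 0.294 and an r of 0.245, at the 99.4th percentile, with 0.392 on plate 1 and 0.187 on plate 2, and 0.305 without the 2 farthest cells. Krt16, a keratin induced in wounds, had a mean of 335 ± 841 CPM and a rho of 0.435, whereas Krt6a and Krt17 had -0.0359 and 0.0175. Of the 10 members of the wound list, 5 had a rho above 0 and 5 below, with a median of -0.000597. None was at 0.3 or above on both plates. The immediate early and heat shock score had a rho of -0.0415 and an r of -0.0854, at the 32.1st percentile, with -0.0345 and -0.0414 on the 2 plates. Its most abundant members were Dnajb1, Ier2 and Hsp90aa1, with means of 178.9, 159.1 and 153.5 CPM. The EGF receptor score had a rho of -0.0636 and an r of -0.0476, at the 30.9th percentile, with -0.0458 and -0.0645 on the 2 plates. Egfr had a rho of -0.239, and Erbb2 and Erbb3 had 0.185 and 0.160.

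**Figure D3:**
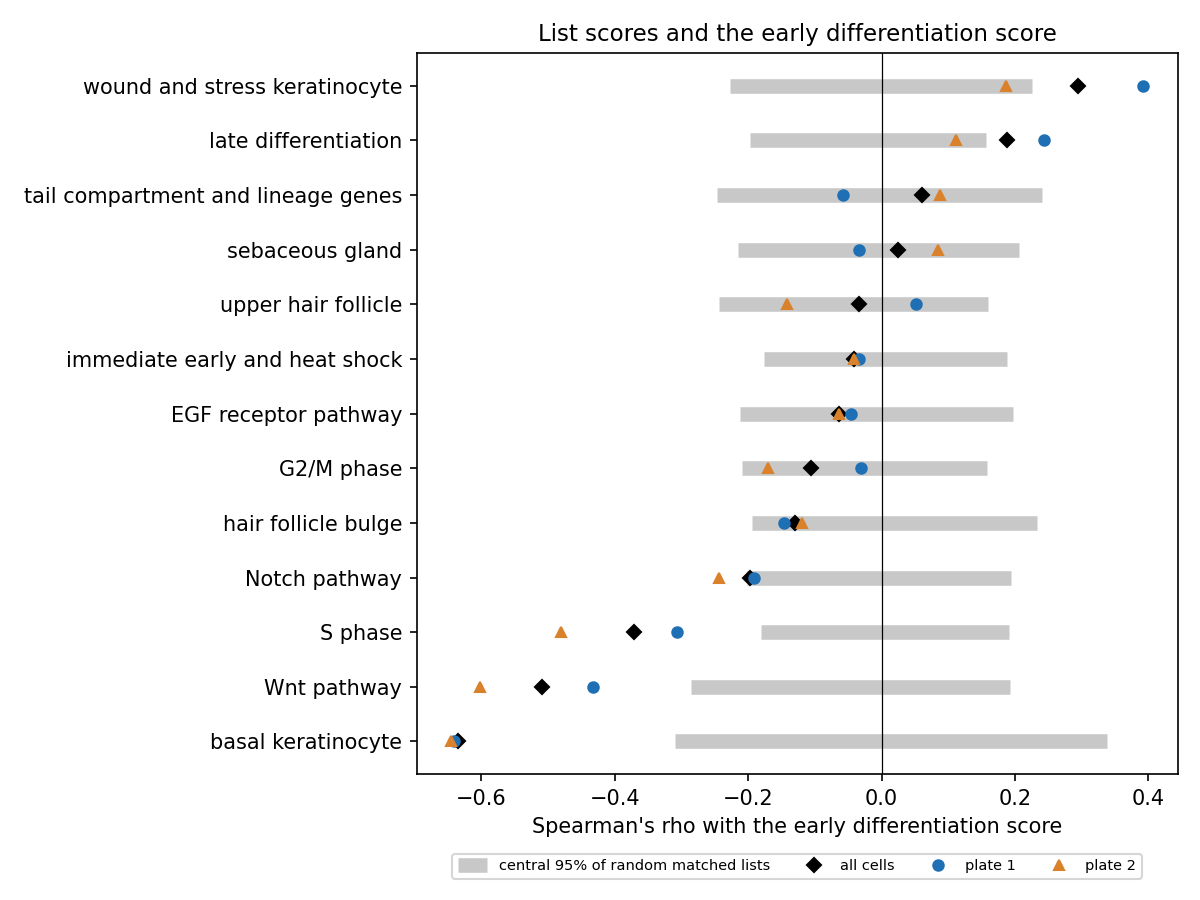
Spearman's rho of 13 list scores with the early differentiation score (horizontal axis) for all cells (diamonds), plate 1 (circles) and plate 2 (triangles), with the central 95% of 10000 random matched lists as grey bars. The basal, Wnt and S phase lists lie below their bars at -0.635, -0.510 and -0.372.

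Krt2, Krt10 and Krt1 varied most beyond technical noise. Of 3685 genes with a mean of 50 CPM or more, 2.82% had a squared coefficient of variation of at least 2 times the spike-in trend on both plates. The 25 highest were led by Krt2, whose smaller ratio to the trend over the 2 plates was 167.4, followed by Krt10 at 128.6, Krt1 at 72.5, Krt14 at 33.4, Mt4 at 28.4 and Krt15 at 26.8. Ly6d, Krtdap, Krt5 and Calm4 had ratios of 19.97, 18.97, 16.7 and 16.6. Krt16 and Krt6a, both wound-induced keratins, had 14.6 and 9.25. Outside the keratinocyte lists, S100a6, Igfbp3, a binding protein of insulin-like growth factors, and Apoe had 10.01, 9.999 and 8.95, Perp, Ccnd2, which encodes cyclin D2, and the imprinted RNA H19 had 7.20, 6.62 and 6.05, and the tubulin gene Tubb5 had 5.89. Dmkn, Malat1, a nuclear long RNA, and Fabp5, a fatty acid binding protein, had 5.70, 5.52 and 5.43. The ribosomal RNA genes mt-Rnr2 and mt-Rnr1 of the mitochondrion had 17.9 and 6.26, and CT010467.1 had 14.9.

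By list, 7 of 9 early differentiation genes tested were variable, 6 of 15 basal genes, 4 of 5 G2/M genes, 3 of 14 S phase genes and 3 of 3 wound genes. None of 7 Wnt, 4 Notch, 8 immediate early or 2 EGF receptor genes was. The rule favours abundant genes, since the spike-in trend had no constant term on either plate. The median mean was 828 CPM among the variable genes and 94.7 CPM among those tested. With the trend fitted to all genes, 41 genes met the rule, of which 39 also met it with the spike-in trend.

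Clustering gave 8 groups of cells, most of which followed the lettered rows of the plates. The adjusted Rand index between clusters and rows, which is 1 for identical groupings and near 0 for unrelated ones, was 0.403, and 64.4% of cells lay in the leading row of their cluster. Of 5 unnamed clusters, those of 19, 12, 19 and 21 cells held 19 cells of row A, 12 of row E, 18 of row D and 17 of row G, and the cluster of 36 cells held 19 of row C and 13 of row H. After subtraction of the background, the index with rows was -0.000288, and -0.00151 and 0.00351 with the fitted and the median rates over genes in up to 3 wells. A cluster of 6 cells still lay only in rows E and F, with 3 cells in each. It was found after subtraction with the rates used and with those median rates. The 5 unnamed clusters of the first grouping are therefore not reported as kinds of cells.

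The early differentiation-like cluster held 35 cells of all 8 rows, 18.6% (95% interval 13.3% to 24.9%), 11 from plate 1 and 24 from plate 2. It was drawn from the same values as its leading genes, Krt10, Zfp750, Ly6g6e, Ly6g6c, 4833423E24Rik, Agpat3, Acer1, Fabp5, Sphk1 and Endou, which therefore describe it without testing it. The G2/M phase-like cluster held 24 cells, 13 of them in row F, and was led by Birc5, Pttg1, Cenpf, Mki67, Ccna2, Cdc20, Racgap1, Ccnb2, Anln and Hmmr. Of its 24 cells, 19 had at least 25% of the G2/M genes at 10 CPM, as 48 cells did over all clusters, so cluster and class differ. A cluster of 22 cells met the rule for S phase, but 17 of them lay in row B and only Uhrf1 and Rrm2 of its 10 leading genes were list members, so its share is not given. After subtraction, 4 of 8 clusters met the naming rule, namely 2 for early differentiation with 27 and 19 cells, 1 for S phase with 48 and 1 for G2/M with 18. The adjusted Rand index between this grouping and the first was 0.205, and it was 0.244 between the first and that of cells thinned to 50000 counts. The first principal component took 5.77% of the variance and had a rho of 0.801 with the early differentiation score, and the second took 3.42% and had a rho of 0.768 with the G2/M score. List genes were not left out of the genes behind the components, so these rho values partly compare genes with themselves.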

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

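Subtraction of the cross-well background, the form of its estimate, centring by plate row, the background limit for Krt10, and leaving out the 2 farthest cells, keratins or a cluster were chosen after the data were seen. A rho was taken to hold if it kept its sign within 0.1, a share if it stayed in its 95% interval, and a count within 1.5 times. The rho of early with late differentiation held in all 16 alternatives (0.109 to 0.259). The rho with the basal score held in 16 of 18, the others being -0.365 without the early differentiation-like cluster and -0.533 after subtraction with median rates over genes in up to 3 wells. The rho with G2/M held in 14 of 16 and was -0.208 after that subtraction and -0.223 with the fitted rates. The gene counts with the early differentiation score held in all 11, from 98 to a total of 59 higher and 79 lower genes in the stricter filter. The share with Krt14 and Krt10 held in 9 of 15, none of which dealt with the background. It was 76.6% after subtraction, and 51.1% and 33.5% with the fitted and the median rates over genes in up to 3 wells. With Krt10 above 3 times its background it was 31.4%, and 27.7% and 25.0% with those rates. The G2/M share held in 7 of 13 and was 93.1% with detection at 1 read, 57.98% and 9.04% with 10% and 50% of the list, and 17.6%, 14.9% and 14.4% after the 3 subtractions. Variable genes numbered 41 with the trend fitted to all genes, 31 at 4 times the trend and 192 after subtraction with the median rates. The number of clusters held in 10 of 11, though their members changed after subtraction; resolution 0.5 gave 5, and each plate by itself kept 94 cells, by construction. Except where the rule or the number of cells itself changed, the cause was not tested. The looser filter and keeping non-keratinocytes removed or added no cell, so they say nothing about stability, nor does scoring all list genes with any read for basal and G2/M, whose members were all in the scores already. In the simulation, genes that changed by 2 were recovered in 28.9% of cases under 50 CPM and in 100% at 50 CPM or more.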

Other observations

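The form of the stray read estimate, the background tests for Krt10, the background and depth tests for the scores and the test of Krt36 against early differentiation were chosen after the results were seen. The tests without keratins, outside the early differentiation-like cluster and of Krt36 with Krt84 were written down before their results.

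Among genes of the tail compartments, Krt36 went with Krt84 but hardly with Krt2 or Krt10. Mouse tail epidermis is divided into scales and interscales. Krt36, a hair-type keratin of tail scales, was at 10 CPM in 62.2% of cells and above background in 70 cells, 37.2%, with a mean of 95.3 ± 311 CPM (SD over all cells). Krt84, a further hair-type keratin, was above background in 68 cells, and Krt2 in 65. Among 66 pairs formed from 12 lineage genes and computed after subtraction of the background, Krt36 and Krt84 had a rho of 0.465 and an r of log2 values of 0.496, and Krt2 and Krt10 had 0.453 and 0.448. Without the 2 cells farthest from the median of the first gene, the rho values were 0.447 and 0.436, whereas over all cells Krt36 had 0.0988 with Krt2 and 0.0794 with Krt10. Slc1a3, a glutamate transporter, reached 10 CPM in 33 cells and Dlx1, a homeobox gene, in 9, and their rho was -0.00872. The tail list as a whole had a rho of 0.0611 and an r of 0.132 with the early differentiation score, at the 71.4th percentile of random lists, with -0.0577 on plate 1 and 0.0880 on plate 2.

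Hair follicle and sebaceous lists did not stand apart from random lists against the early differentiation score. The upper hair follicle list had a rho of -0.0340 and an r of -0.0691, at the 47.97th percentile, with 0.0521 and -0.142 on the 2 plates. Its rho was 0.0589 with log2(CPM + 10) and 0.117 with cells thinned to 50000 counts. The bulge list had a rho of -0.129 and an r of -0.156, at the 9.55th percentile, with -0.146 and -0.120 on the plates. The sebaceous gland list had 0.0238 and 0.0449, at the 60.5th percentile, with -0.0346 and 0.0849. Within the upper follicle list, Cst6, a cysteine protease inhibitor, had a rho of 0.305 with the score, and Plet1 had -0.144. In the bulge list, Postn, a matrix protein with a mean of 158.9 ± 180.9 CPM, and Col18a1, a basement membrane collagen with 130.4 ± 140.9 CPM, had -0.383 and -0.288, while Sox9 and Krt24 had 0.225 and 0.157. The genes Fasn and Scd1 of fatty acid synthesis, with means of 137.9 and 89.5 CPM, made up most of the sebaceous counts.

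Krt10 reads were found in every well, and reads exchanged between wells of the same lettered row, taken to share an index although no label gives the index layout, may account for most of the low counts. Stray reads of single-well genes were 30.2 times as frequent in the same row as in unrelated wells, and 5.89 to 12.3 times in the 4 other forms of the estimate, so the form used gave the highest ratio. Per 10000 source reads they were 26.5 in the same row of the same plate and 28.6 in that row of the other plate. Over the 8 rows, the median Krt10 count of the lower 50% of wells followed the row's Krt10 total, with a Spearman correlation of 0.976 and a Pearson correlation of 0.963, and lay at a median of 1.11 times the expected background, or 0.557 to 0.811 times in the other forms, so its nearness to 1 is no independent evidence. Low Krt10 expression in every basal cell remains open, although 31.4% of wells exceeded 3 times the background against the 90% set as the sign of such expression, since the other wells would keep a median of 113.7 CPM after subtraction with the rates used, 388 CPM with these rates at their lower quartile, and 0 with each of the 4 other forms.

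Early differentiation and basal scores moved in opposite directions. The tables argue against exchanged reads as the whole cause, since rho was -0.599 after subtraction and -0.533 with the highest of the stray rates in unrelated wells, against the depth of the wells, with -0.632 after adjustment for genes detected, and against displacement by abundant keratins, with -0.582 when keratins were left out of lists and totals. Whether the relation may rest on the cells of the early differentiation-like cluster stays open, because rho in the other clusters was -0.365 but only -0.195 on plate 2, and leaving out the cells with the highest scores narrows the range. No biological explanation was tested, since the design has 1 group.

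Krt36 reads were found in a part of the cells. That Krt36 follows early differentiation is argued against by a rho of 0.0657 on plate 2 and -0.118 on plate 1 after subtraction. A candidate explanation is that Krt36 and Krt84 mark the same cells, since the smaller rho of the 2 plates was 0.448. This was found and tested on the same cells, and whether these cells lie in scales was not measured.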
